A study of Homo sapiens with 4 samples.

How the data were processed

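RNA was measured in 4 T47D libraries, 2 from untreated controls and 2 from baicalein-treated samples. Dose, duration and vehicle of the treatment are not given in the sources used here. Per the labels, poly(A) RNA was isolated with magnetic beads and libraries followed standard Illumina protocols. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3, DESeq2 1.34 and the genome build GRCh38, without saying which step each served. The annotation release and the use of strand in counting are not given in the sources used here. The authors deposited whole-number counts per gene in 1 table of 20515 rows, with no scaling to library size. Whether they are RSEM estimates rounded to whole numbers is not stated, and if so they carry assignment error for genes that share reads. The smallest row total over the 4 libraries was 10, so genes with fewer counts were not analysed here. The table holds 0 columns of other samples.

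Columns were matched to samples by the sample descriptions, and groups and replicate numbers were taken from the sample titles. Rows carry Ensembl identifiers, of which 20470 matched the reference names table and 17419 had a symbol there. Coordinates, gene types and exon overlaps were taken from GENCODE release 29 on GRCh38, which held 19849 of the identifiers and may not be the authors' release. In 2 sets, 5 rows with a total of at least 1000 held identical counts.

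Total counts were 45341857 and 45618604 in the controls and 56732569 and 38597207 in the treated libraries. A floor of 3 counts corresponds to 0.0549 to 0.0805 CPM, and it covers counting error only, as reads without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise, with a mean chi-square per gene of 9.61 (median 1.39) over 17891 genes in controls and 2.43 (median 0.7) over 17862 genes in treated libraries (pairs with at least 20 counts). This served only to check whether the columns of a group repeat the same library, and does not show that libraries came from separate cultures. The common biological coefficient of variation was 0.0383.

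Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust settings and its F test) over all 4 libraries without covariates. Scaling used TMM factors (1.042, 1.031, 0.964 and 0.965), and filterByExpr with a minimum count of 10 and a minimum total of 15 kept 18369 genes and left out 2146. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. CPM values are scaled by the TMM factors. The standard error of a log2 fold change is its size divided by the square root of F. Gene lists with at least 5 tested members (33 of 36) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry stood beside it. The lists held 612 tested memberships of 589 genes, 23 of them in at least 2 lists.

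The design, lists, alternatives and rule for named genes were set before the data were examined. The rule names the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, a symbol and both treated libraries on one side of both controls. It adds up to 4 members per list by the smallest adjusted p, a fixed set of targets and markers (among them ALOX12, ALOX15, ESR1, PGR, CDKN1A, MKI67, CYP1A1, CYP1B1, HMOX1 and TFRC) and the 3 most abundant genes. Some genes that the rule names are not reported here. Genes named outside it were chosen after their values were seen, as were RN7SK, MX1, IFI6 and IFIT1. Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), no filter or a filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom, a threshold of 0.01, a test against a 1.5-fold change, the replicate number as a block and leaving out each library. A correction for GC content and exon length, as a trend in each library, was added after seeing the data and used the 17867 tested genes with both values. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group.

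The methods were tested on simulated data with known changes for this comparison, drawn at the real control means, depths and dispersions (17697 genes for single genes and 17662 for lists). Of 50 genes each changed by 1.2, 1.5, 2 and 4 fold, 44%, 82%, 90% and 98% were called in the right direction. The changed genes were drawn only from genes above a minimum expected control count, so recovery at lower counts was not measured. Of 17497 unchanged genes 22 were called, among 179 calls in all. This share of false calls was above the adjusted p threshold of 0.05. Camera called 3 of 3 lists shifted by 0.5 log2 units and 0 of 26 lists without shifted genes. The simulated genes varied independently of each other and only members of the 3 lists were shifted. The list simulation therefore cannot show whether the preset correlation suits these libraries. Figures were drawn with matplotlib 3.10.9.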

Results

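Poly(A) RNA was sequenced from T47D cells, an established line of human luminal breast carcinoma cells that carry estrogen and progesterone receptors. The 4 libraries came from 2 control samples without treatment and 2 samples treated with baicalein, a plant flavonoid known as a lipoxygenase inhibitor. The comparison asked which genes differ in expression after baicalein. Total counts were 45341857 and 45618604 in control 1 and 2, and 56732569 and 38597207 in baicalein 1 and 2, so that 1 CPM stood for 37.2 to 54.7 counts. Libraries of one group correlated at r = 0.9945 (control) and 0.9946 (baicalein) over the log2 CPM of genes, and pairs from different groups at 0.9318 to 0.9357. Control 1 stood apart from control 2 in RN7SK, a non-coding RNA without a poly(A) tail, with 7.35 times its level. Levels are given as mean CPM ± SD (n = 2 libraries per group) and fold changes as baicalein over control. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

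Baicalein-treated cells expressed the xenobiotic-metabolising enzyme CYP1A1 at 1502 times the control level and genes of DNA replication at lower levels, with all 30 tested members of that list below control in edgeR's test. The estrogen receptor gene ESR1 fell 4.60-fold and the progesterone receptor gene PGR 8.31-fold. Of the genes of the amino acid stress response 21 of 23 were higher, of endoplasmic reticulum protein folding 14 of 16, of antioxidant defence 19 of 20 and of cholesterol synthesis 20 of 24. Each of these lists had adjusted p = 0.313 with an estimated correlation. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6866 of 18369 tested genes were higher and 6902 lower, and 4601 did not pass. At least 2-fold changes were found in 2244 of the higher and 2791 of the lower genes, and at least 10-fold changes in 250 and 146. Of the called genes, 2859 higher and 2480 lower ones changed by less than 1.5-fold, and a test against a 1.5-fold change called 3090 and 3581. Among 13972 protein-coding genes 5472 were higher and 5855 lower, and among 2619 long non-coding genes 886 and 627.

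**Figure D1:**
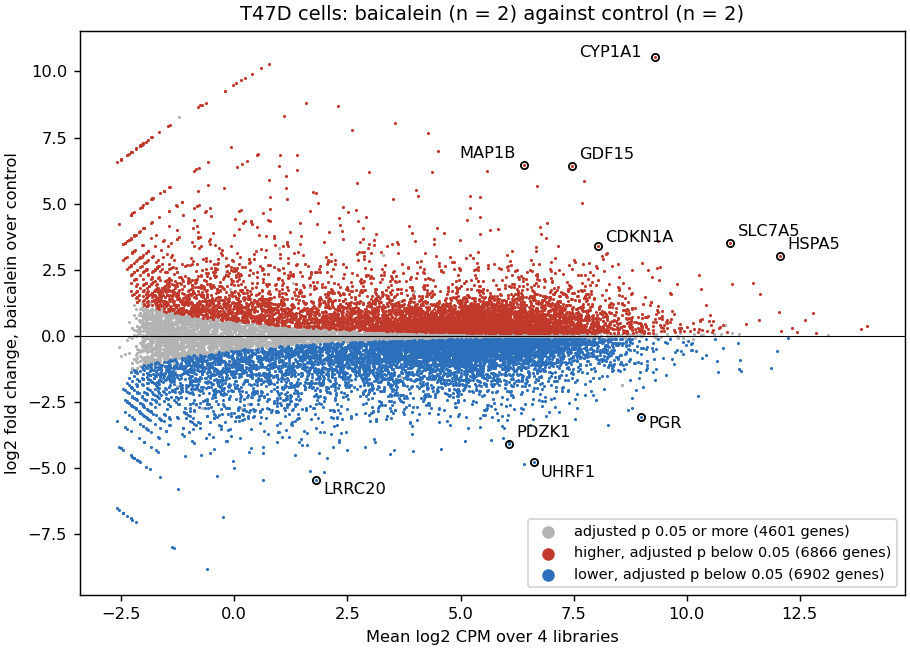
Log2 fold change (baicalein over control) against mean log2 CPM over the 4 libraries, 1 point per tested gene, coloured by the call at an adjusted p of 0.05 in edgeR's quasi-likelihood test. The 6866 higher and 6902 lower genes lie at all expression levels, with CYP1A1 at 10.55 and UHRF1 at -4.77.

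CYP1A1 (ENSG00000140465, chromosome 15, positions 74719542 to 74725610 of GRCh38) rose from 0.838 ± 0.102 to 1263 ± 72.0 CPM, a log2 fold change of 10.55 (SE 0.08, adjusted p = 2.82e-28). Among the 12 largest rises by the naming rule, GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, positions 18374731 to 18389176), rose from 4.10 to 351 CPM with a log2 fold change of 6.42 (SE 0.10). The microtubule-associated protein gene MAP1B rose from 1.92 ± 0.189 to 169 ± 6.15 CPM. RAB39B rose from 1.27 ± 0.244 to 95.3 ± 5.29 CPM, FIBIN from 0.350 ± 0.0762 to 45.3 ± 0.0342 CPM, and LCN2, which codes for the iron-siderophore carrier lipocalin, from 0.191 ± 0.0594 to 39.1 ± 1.89 CPM. KLHDC7B, CLIP4 and SCEL had log2 fold changes of 8.06, 6.84 and 6.26 from control levels below 0.1 CPM. For the gene CLIP4, with 3 and 1 counts in control 1 and 2, the value was 7.75 without control 1. NPHS1, CMKLR2 and MOV10L1 had 1, 2 and 3 counts over both control libraries, so their ratios are given with 95% exact binomial intervals that cover counting error only. These ratios were 560 (100 to 22200), 459 (127 to 3790) and 124 (42.1 to 604). All of these control counts were in control 1, so without that library no ratio can be formed for the 3 genes. The largest falls included UHRF1, which codes for a factor of DNA methylation maintenance (ENSG00000276043, chromosome 19, positions 4903080 to 4962154), from 188 ± 4.49 to 6.85 ± 0.346 CPM (log2 fold change -4.77, SE 0.06, adjusted p = 9.52e-25). LRRC20 and NDST4 had the most negative log2 fold changes under that rule, -5.44 and -5.10, and FAM111B fell from 163 ± 9.25 to 5.75 ± 0.220 CPM. In baicalein 1 and 2, LRRC20 had 8 and 6 counts and NDST4 10 and 6. Their values (SE 0.21 each) are thus less precise than that of UHRF1. The other falls were in RIBC2 (-4.62), KCTD12 (-4.49), CNIH2 (-4.46), EGR3 (-4.43), the replication regulator E2F2 (-4.37), NRGN (-4.31), RANBP3L (-4.30) and the replication checkpoint adaptor CLSPN (-4.29). RIBC2 had 19 and 10 counts and KCTD12 12 and 7 in baicalein 1 and 2 (SE 0.19 and 0.22). For the gene EGR3, with 23 and 6 counts in baicalein 1 and 2, the value was -5.37 without baicalein 1. Exons of CNIH2 overlap those of YIF1A on the opposite strand and exons of NPHS1 those of APLP1 and KIRREL2. Exons of CYP1B1, PGR and CDKN1A, described below, overlap those of CYP1B1-AS1, PGR-AS1 and DINOL in the same way. Whether counting used strand is not given in the sources used here.

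The gene lists below were fixed in advance, and counts adjusted over the list alone equalled those over all genes except where both are printed. Their camera test asks whether a list moved relative to the other genes, with a preset correlation between genes of 0.01 or with one estimated from these libraries. All 6 tested targets of the aryl hydrocarbon receptor (AhR), a ligand-activated sensor of planar aromatic compounds, were higher (median log2 fold change 3.34, camera adjusted p = 0.00147, adjusted p = 0.354 with an estimated correlation). CYP1B1 (ENSG00000138061, chromosome 2, positions 38066973 to 38109902) rose from 101 ± 7.59 to 1219.8 ± 40.7 CPM, and TIPARP, which codes for a repressor of the receptor, from 28.9 ± 1.48 to 127 ± 3.62 CPM. Of 20 targets of the oxidative stress regulator NRF2, 19 were higher and 1 did not pass (camera adjusted p = 5.08e-07, adjusted p = 0.313 with an estimated correlation). The cystine transporter gene SLC7A11 rose from 11.7 ± 1.31 to 229 ± 4.16 CPM and the sulfiredoxin gene SRXN1 from 67.4 ± 0.109 to 505 ± 23.2 CPM. TXNRD1 and HMOX1, which code for thioredoxin reductase and heme oxygenase, had log2 fold changes of 2.48 and 2.15. NQO1, a member of both lists, rose from 209 ± 3.04 to 447 ± 2.07 CPM. Of 12 iron-handling genes 7 were higher and 5 lower (camera adjusted p = 0.374). The ferritin genes FTH1 and FTL rose 3.85-fold and 4.50-fold, the transferrin receptor gene TFRC had a log2 fold change of 0.29, and STEAP3, which codes for a ferrireductase, fell with -1.58. Among 9 genes of flavonoid conjugation and efflux, 4 were higher and 4 lower (camera adjusted p = 0.959, median -0.23, mean 0.13, direction of the test up, but down without control 1). The efflux pump genes ABCC1 and ABCC3 rose with log2 fold changes of 0.81 and 1.12, and the conjugating enzyme gene GSTM3 fell with -1.36. ABCC3 is also in the NRF2 list. The metallothionein list had 4 tested members, too few for camera, with 1 higher and 2 lower. MT2A fell with a log2 fold change of -0.83, and MT1X had 0.11, which did not pass. The call of MT1F (-0.94, adjusted p = 0.0206) was lost without control 1 (adjusted p = 0.098), without baicalein 2 (0.155) and in DESeq2 (0.197).

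All 30 tested genes of G1/S and DNA replication were lower (median log2 fold change -2.70, camera adjusted p = 1.07e-12, adjusted p = 0.313 with an estimated correlation). RRM2, which codes for the small subunit of ribonucleotide reductase, fell from 332 ± 7.95 to 37.6 ± 1.11 CPM. The replication licensing gene MCM3 fell from 255 ± 6.93 to 34.9 ± 0.287 CPM, and E2F1 from 114 ± 4.83 to 7.88 ± 0.176 CPM. All 30 tested G2/M and mitosis genes were lower as well (median -1.43, camera adjusted p = 1.73e-10, adjusted p = 0.313 with an estimated correlation). The proliferation marker MKI67 (ENSG00000148773, chromosome 10, positions 128096659 to 128126385) fell from 384 ± 5.05 to 90.9 ± 4.34 CPM. The mitotic kinesin gene KIF20A fell from 82.1 ± 2.03 to 13.2 ± 0.359 CPM, and ASPM and NUSAP1 had log2 fold changes of -2.06 and -2.06. Of 20 genes of homologous recombination and the Fanconi pathway, 19 were lower and 1 higher (median -1.85, camera adjusted p = 5.08e-07, adjusted p = 0.313 with an estimated correlation). BRIP1 fell from 46.6 ± 1.86 to 5.02 ± 0.193 CPM, FANCI from 195 ± 3.01 to 39.8 ± 1.18 CPM, and FANCD2 and EXO1 had log2 fold changes of -1.84 and -2.28. Replication-dependent histone genes went the other way, with 11 of 15 higher and 2 lower, or 11 and 3 adjusted over the list alone (median 1.44, camera adjusted p = 0.019, adjusted p = 0.632 with an estimated correlation). H4C8 rose from 4.19 ± 0.241 to 28.9 ± 0.800 CPM, H2BC21 from 16.7 ± 0.591 to 99.1 ± 1.82 CPM and H2AC6 from 19.6 ± 1.56 to 85.4 ± 1.64 CPM. The gene of the variant histone H2AX fell from 289.6 ± 4.55 to 90.6 ± 2.71 CPM. Reads shared between near-identical histone copies make the split among single histone genes uncertain. Of 7 genes for inhibitors of cyclin-dependent kinases, 3 were higher and 2 lower (camera adjusted p = 0.734, median -0.08, mean 0.44, direction of the test up, and the median turned to 0.26 with GC content and length corrected). CDKN1A (ENSG00000124762, chromosome 6, positions 36676460 to 36687339), which codes for p21, rose from 45.3 ± 1.13 to 484 ± 20.4 CPM. CDKN2B and CDKN1B had log2 fold changes of 2.53 and 0.64, whereas CDKN2C fell from 49.8 ± 0.404 to 8.56 ± 0.103 CPM. Of 23 p53 targets, CDKN1A among them, 17 were higher and 4 lower (camera adjusted p = 0.00245, adjusted p = 0.313 with an estimated correlation). TNFRSF10B, which codes for a death receptor, rose from 52.0 ± 1.89 to 302 ± 6.45 CPM, SESN2 from 28.2 ± 2.01 to 149 ± 2.45 CPM and RRM2B from 75.5 ± 5.23 to 212 ± 4.72 CPM.

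Of 29 estrogen-induced genes 22 were lower and 5 higher, or 23 and 5 adjusted over the list alone (median -0.90, camera adjusted p = 0.000331, adjusted p = 0.313 with an estimated correlation). PGR (ENSG00000082175, chromosome 11, positions 101029624 to 101130524) fell from 911 ± 23.3 to 109.5 ± 4.43 CPM. The scaffold gene PDZK1 fell from 127 ± 1.85 to 7.37 ± 0.821 CPM and the carbonic anhydrase gene CA12 from 735 ± 4.27 to 145 ± 3.68 CPM. AREG, which codes for the growth factor amphiregulin, rose from 94.5 ± 1.03 to 387 ± 10.3 CPM. Of 17 luminal epithelial genes 11 were lower and 3 higher (camera adjusted p = 0.0486, adjusted p = 0.323 with an estimated correlation). With the replicate number as a block this list missed the threshold as well. The call of the list luminal epithelial genes was also lost without control 1 (adjusted p = 0.0506), without baicalein 1 (0.0645) and without baicalein 2 (0.0622). ESR1 (ENSG00000091831, chromosome 6, positions 151656691 to 152129619) fell from 177 ± 8.30 to 38.5 ± 1.01 CPM (log2 fold change -2.20, SE 0.05, adjusted p = 7.47e-21). The lineage factor gene GATA3 fell from 1098 ± 51.0 to 393 ± 29.6 CPM and the prolactin receptor gene PRLR from 2405 ± 131 to 925 ± 31.8 CPM. Of 11 progestin and glucocorticoid induced genes 6 were higher and 4 lower (camera adjusted p = 0.455). TSC22D3 rose from 13.7 ± 0.840 to 47.2 ± 0.485 CPM, and ERRFI1 and EDN1 had log2 fold changes of 1.11 and 0.80, whereas FKBP5 fell from 182 ± 3.71 to 91.9 ± 1.33 CPM. Basal breast epithelial markers were 3 higher and 4 lower of 9 (camera adjusted p = 0.766, median -0.20, turning to 0.07 with GC content and length corrected). EGFR rose from 28.4 ± 0.753 to 68.2 ± 1.81 CPM and FOXC1 from 10.7 ± 0.170 to 24.8 ± 0.924 CPM. TP63, a basal lineage factor gene, fell from 5.04 ± 0.602 to 0.348 ± 0.0779 CPM and ITGB4 from 228 ± 13.8 to 97.4 ± 3.52 CPM.

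**Figure D2:**
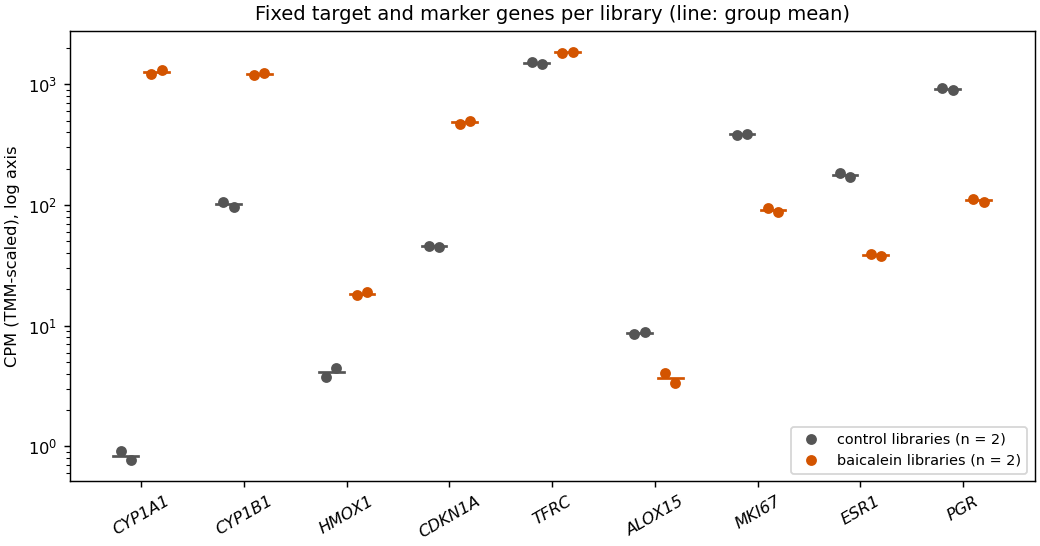
TMM-scaled CPM per library on a log axis for target and marker genes from a set fixed in advance, with 2 control and 2 baicalein libraries per gene and lines at the group means. CYP1A1 lies at 0.838 CPM in controls and 1263 CPM with baicalein, and ESR1 and PGR fall to 38.5 and 109.5 CPM.

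Of 23 genes of the transcription factor ATF4 and the amino acid response, 21 were higher and 1 lower (median 2.40, camera adjusted p = 2.77e-07, adjusted p = 0.313 with an estimated correlation). The amino acid transporter gene SLC7A5 rose from 322 ± 4.49 to 3666 ± 80.4 CPM. PPP1R15A, which codes for a regulator of eIF2 dephosphorylation, rose from 16.9 ± 1.06 to 222 ± 1.82 CPM, and ATF3 from 14.2 ± 0.0915 to 205 ± 6.61 CPM. SLC7A11 and SESN2 belong to this list and to the NRF2 and p53 lists, respectively. Of 16 endoplasmic reticulum chaperone and folding genes, 14 were higher and 2 lower (camera adjusted p = 0.00024, adjusted p = 0.313 with an estimated correlation). HSPA5 (ENSG00000044574, chromosome 9, positions 125234853 to 125241330), which codes for the chaperone BiP, rose from 946 ± 20.4 to 7604 ± 246 CPM. The stress sensor gene ERN1 rose from 18.2 ± 0.450 to 186 ± 0.778 CPM, DNAJB9 from 14.2 ± 1.29 to 118 ± 0.292 CPM and HERPUD1 from 32.8 ± 0.417 to 225 ± 0.152 CPM. Cytosolic heat shock genes were lower in 13 of 14 cases (camera adjusted p = 0.01, adjusted p = 0.313 with an estimated correlation). HSP90AA1 fell from 3360.2 ± 39.6 to 1347 ± 3.69 CPM, HSPB1 from 502 ± 37.7 to 244 ± 2.77 CPM and DNAJA1 from 148 ± 5.65 to 69.5 ± 1.09 CPM. The exception HSPD1, which codes for a mitochondrial chaperonin, had a log2 fold change of 0.95. HSPE1, which codes for the mitochondrial partner of HSPD1, fell with -0.19, so the list is not purely cytosolic. Of 25 apoptosis regulators 14 were higher and 7 lower (camera adjusted p = 0.172). The pro-apoptotic genes HRK and BBC3 rose from 0.615 ± 0.0920 to 22.4 ± 1.52 CPM and from 3.59 ± 0.282 to 19.8 ± 1.45 CPM, and BIRC5 and BID fell with log2 fold changes of -1.91 and -1.53. BBC3 is also a p53 list member and BIRC5 a mitosis list member. Autophagy and lysosome genes were higher in 15 and lower in 4 of 23 cases, or 15 and 5 adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.313 with an estimated correlation). MAP1LC3B rose from 58.6 ± 0.222 to 398 ± 10.7 CPM and the autophagy receptor gene SQSTM1 from 209 ± 8.40 to 987 ± 22.6 CPM. NEU1 and WIPI1 had log2 fold changes of 1.94 and 1.37.

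Cholesterol synthesis genes were higher in 20 and lower in 4 of 24 cases (median 1.93, camera adjusted p = 2.77e-05, adjusted p = 0.313 with an estimated correlation). HMGCS1 rose from 132 ± 7.85 to 902 ± 23.7 CPM and MSMO1 from 31.0 ± 0.513 to 242 ± 5.10 CPM. The squalene epoxidase gene SQLE and MVD had log2 fold changes of 2.64 and 2.57. Of 11 fatty acid synthesis genes 6 were higher and 2 lower (camera adjusted p = 0.0869, and 0.033 with GC content and length corrected). The desaturase gene SCD rose from 1130.2 ± 40.2 to 4542 ± 62.0 CPM and ACSL3 from 117 ± 3.41 to 354 ± 6.68 CPM. ACSS2 and ACLY, which code for enzymes that make acetyl-CoA, had log2 fold changes of 1.46 and 0.32. Glycolysis genes were 5 higher and 12 lower of 18 (camera adjusted p = 0.266). HK2 rose from 17.3 ± 0.567 to 73.5 ± 3.96 CPM and ALDOC from 40.2 ± 2.32 to 90.5 ± 4.09 CPM, and PGAM1 fell from 439 ± 1.91 to 234 ± 6.99 CPM. Of 22 targets of the hypoxia-inducible factors (HIF) 13 were higher and 7 lower (camera adjusted p = 0.0619). This list passed the threshold without a filter, with library totals alone, with GC content and length corrected and without baicalein 1. NDRG1 rose from 1.88 ± 0.0989 to 73.2 ± 7.45 CPM, and the angiogenic factor gene VEGFA had a log2 fold change of 3.02. The demethylase gene KDM3A and the glucose transporter gene SLC2A1, which the glycolysis list shares, had 1.74 and 1.47. Nuclear-encoded oxidative phosphorylation genes were lower in 27, not passing in 5 and higher in 0 of 32 cases (median -0.40, camera adjusted p = 4.89e-05, adjusted p = 0.313 with an estimated correlation). ATP5MC1 fell from 59.4 ± 0.570 to 22.5 ± 1.58 CPM, NDUFA2 from 45.8 ± 0.585 to 18.8 ± 1.45 CPM, NDUFA4 from 81.9 ± 6.74 to 40.9 ± 1.54 CPM and SDHA from 332 ± 15.8 to 182 ± 3.07 CPM. The 13 mitochondrially encoded genes were 7 higher and 2 lower (camera adjusted p = 0.261), and 1 and 1 with GC content and length corrected. They include the most abundant genes, MT-CO1 (14188 ± 1251 CPM in controls, 18261 ± 56.2 with baicalein), MT-ND4 (13413 ± 793 and 16252 ± 250.4) and MT-ND2 (8890.4 ± 286 and 9067 ± 336, which did not pass, adjusted p = 0.499). For the gene MT-ND2 the adjusted p was 0.0234 without control 2. The calls of MT-CO1 and MT-ND4 were lost under the GC content and length correction (adjusted p = 0.111 and 0.137), whereas MT-CYB rose from 5000.1 ± 132 to 7567 ± 296 CPM and MT-CO3 fell from 4823 ± 439 to 3288 ± 163 CPM. All mitochondrially encoded genes, including ribosomal RNA outside this list such as MT-RNR2, took 7.95% and 8.38% of the counts in the controls. The shares with baicalein were 9.16% and 8.89%.

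Cytosolic ribosomal protein genes showed small shifts, with 30 of 36 higher and 2 lower (median 0.20, camera adjusted p = 0.00162, adjusted p = 0.372 with an estimated correlation), and 18 higher and 3 lower when scaled by library totals alone. RPLP0, RPL10, RPL37 and RPL5 had log2 fold changes of 0.43, 0.46, 0.43 and 0.38. Of 25 ribosome biogenesis genes 16 were higher and 6 lower (camera adjusted p = 0.0574). The helicase gene DDX21 rose from 299 ± 1.74 to 623 ± 9.56 CPM, RRP12 and GNL3 had log2 fold changes of 1.10 and 0.71, and NOP56 fell from 219 ± 9.96 to 108 ± 2.59 CPM.

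Type I interferon response genes were lower in 14, higher in 6 and not passing in 8 of 28 cases (median -0.84). Their camera adjusted p was 0.0519, and under 0.05 with the replicate block, without a filter and with GC content and length corrected. In some of these genes the control libraries differed, with control 1 over control 2 ratios of 1.45 for MX1, 1.62 for IFI6 and 2.04 for IFIT1, whereas OAS3 (144 and 137 CPM) and BST2 (179 and 184 CPM) were close in control 1 and 2. The adjusted p of the list type I interferon response was 0.058 without control 1 and 0.00529 without control 2. OAS3 fell from 140.5 ± 4.52 to 21.4 ± 0.309 CPM, BST2 from 181 ± 3.50 to 82.2 ± 0.598 CPM, and USP18 and the RNA sensor gene RIGI had log2 fold changes of -1.48 and -1.56. Of 13 NF-kB targets 8 were higher and 2 lower (camera adjusted p = 0.0254, adjusted p = 0.313 with an estimated correlation), and the call was lost without control 2 (adjusted p = 0.0834). RELB rose from 3.43 ± 0.154 to 22.8 ± 0.0724 CPM and TNFAIP3 from 1.56 ± 0.0999 to 9.56 ± 0.00327 CPM. The adhesion molecule gene ICAM1 and IER3 had log2 fold changes of 2.21 and 1.66. Immediate early genes were 12 higher and 5 lower of 19 (camera adjusted p = 0.107). KLF6 rose from 40.8 ± 0.0161 to 162 ± 2.22 CPM, and EGR3, described above, is shared with the estrogen list. Of 8 lipoxygenase and cyclooxygenase pathway genes 2 were higher and 3 lower (camera adjusted p = 0.715). The prostaglandin synthase gene PTGES fell from 98.1 ± 0.443 to 13.0 ± 0.618 CPM, and ALOX15 from 8.70 ± 0.239 to 3.70 ± 0.452 CPM. LTA4H and ALOXE3 had log2 fold changes of 0.29 and 0.45, while ALOX12 was not analysed here. WNT targets were 2 higher and 2 lower of 6 (camera adjusted p = 0.766, median 0.09, turning to -0.02 with library totals alone). RNF43 and NKD2 rose with log2 fold changes of 1.52 and 1.24, and TCF7 and ZNRF3 fell with -1.96 and -0.34. Of 8 mesenchymal transition genes 1 was higher and 3 lower (camera adjusted p = 0.561). FN1 fell from 30.8 ± 0.971 to 18.4 ± 0.982 CPM, TWIST1 and CDH2 had log2 fold changes of -1.25 and -1.71, and ITGA5 rose from 13.2 ± 0.227 to 17.5 ± 0.0846 CPM. The fibroblast and immune cell markers each had 3 tested members, too few for camera, with 2 higher and 1 lower and with 1 higher and 1 lower, respectively. COL1A1 rose from 95.2 ± 7.32 to 145 ± 7.13 CPM, LUM had 0.265 ± 0.0141 CPM in controls and 1.05 ± 0.0354 with baicalein, and THY1 0.329 ± 0.136 and 0.0451 ± 0.0121. The fibroblast list's median was 0.61 and its mean -0.09. CD8A rose from 0.541 ± 0.0768 to 1.17 ± 0.174 CPM, and CD68 had a log2 fold change of -0.10, which did not pass (adjusted p = 0.825). The immune list's median of -0.10 turned to 0.02 with GC content and length corrected.

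**Figure D3:**
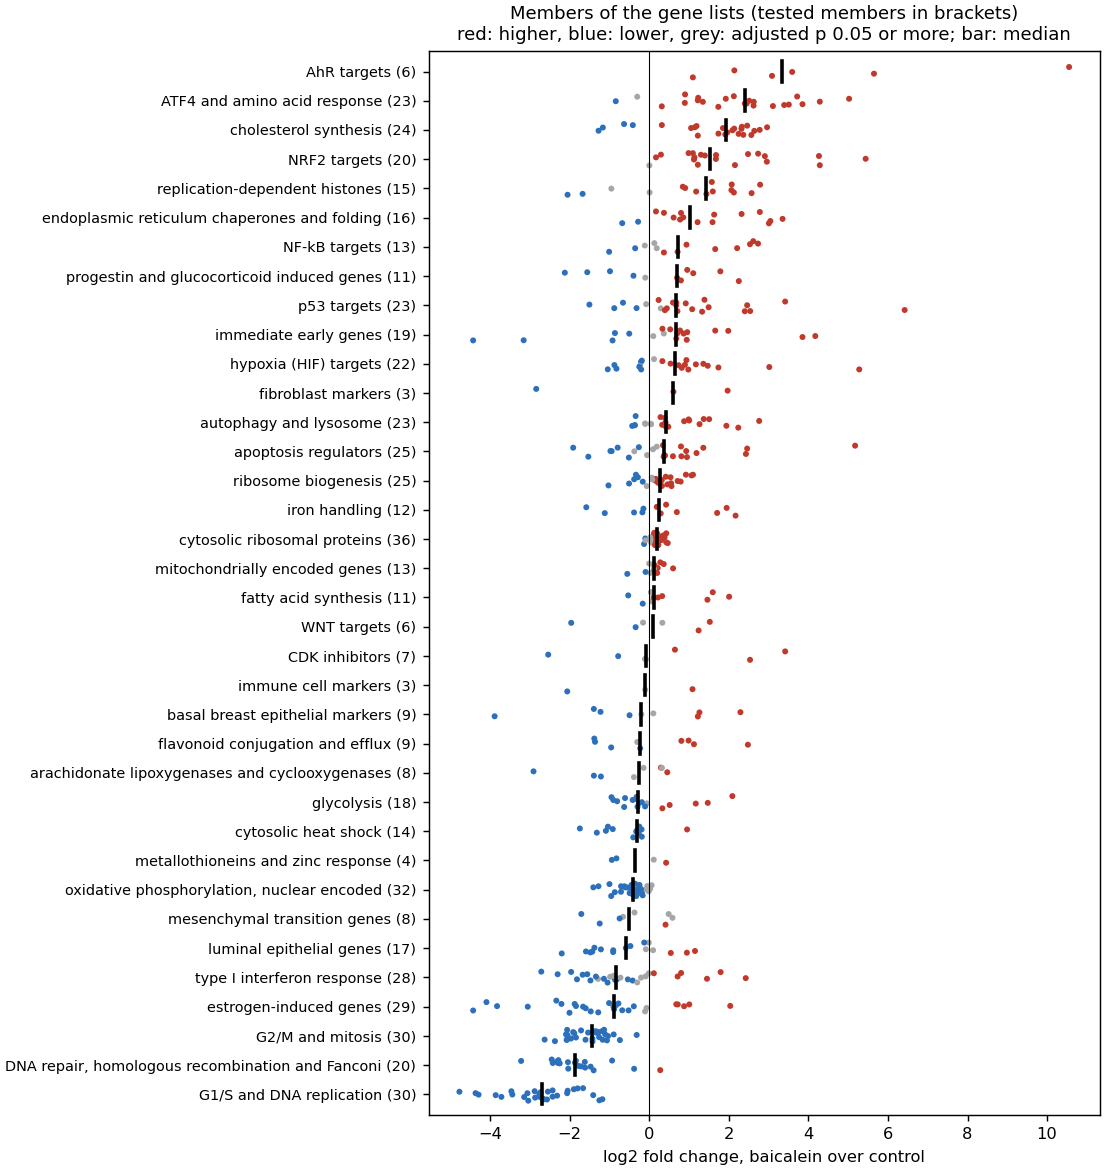
Log2 fold changes (baicalein over control) of the tested members of each gene list, 1 point per gene, with bars at the list medians and colours for the call at an adjusted p of 0.05. The medians run from -2.70 for G1/S and DNA replication to 3.34 for AhR targets.

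Of the 33 lists large enough for camera, 10 were called higher and 7 lower. With an estimated correlation, which 2 residual degrees of freedom leave imprecise, camera called 0 in either direction, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.313. The test fry, which asks whether a list's genes move on balance one way and compares them with no other genes, called 19 lists higher and 10 lower.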

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

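Of the alternatives here, the GC content and length correction was chosen after seeing the data, and the others were planned. Counts of 6866 higher and 6902 lower genes stayed within 1.5 times, from 5928 to 7088 and from 5973 to 7735, under every setting run except the test against a 1.5-fold change, which called 3090 and 3581 by its stricter construction. Library totals alone shifted the median log2 fold change of all genes by -0.10 and gave 43.4% higher among the called genes, against 49.9%. No gene called in the comparison above was called in the opposite direction under any of these settings except the GC and length correction, where 117 were. DESeq2 called 5932 and 5973, and limma-voom 6857 and 6898. Without 1 library the counts ran from 6128 to 6944 higher and from 6294 to 6896 lower. Nothing in the labels pairs libraries by replicate number, and the deviations of same-numbered libraries correlated at 0.014. With the replicate block 6894 genes were higher and 6909 lower, 10 lists higher and 7 lower, the list luminal epithelial genes missed the threshold (adjusted p = 0.0534) and the list type I interferon response passed it (0.0475).

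Of the 162 named genes, 157 kept direction and side of the 0.05 threshold under every setting that was compared gene by gene and tested them. The test against a 1.5-fold change and the threshold of 0.01 were left out of that comparison. Calls of small changes cannot be taken to hold under these 2 settings. The genes MT-CO1 and MT-ND4 and the gene MT1F lost calls as given above, MT1F also under the GC and length correction (adjusted p = 0.0536). The gene CD68, which did not pass, ran from -0.2506 without baicalein 2 to 0.0907 without baicalein 1, with 0.0522 without control 2 and 0.0225 with the GC and length correction. The gene MT-ND2, which did not pass either, turned to -0.0035 (upper quartile), -0.075 (library totals), -0.0069 (without control 1), -0.0041 (without baicalein 1) and -0.0559 (GC and length), with 0.075 without baicalein 2 and 0.067 without control 2, where it passed (adjusted p = 0.0234). Lists called went from 10 higher and 7 lower to 0 and 0 with an estimated correlation, 19 and 10 with fry, which asks another question, and 9 to 11 and 6 to 8 without 1 library. Uncalled lists that changed direction were the list flavonoid conjugation and efflux (adjusted p = 0.103 by fry, 0.942 without control 1, while 0.891 without control 2 kept it) and the list WNT targets (0.964 without a filter, 0.942, 0.526, 0.686 and 0.861 without control 1, control 2, baicalein 1 and baicalein 2). The list hypoxia (HIF) targets passed without a filter (0.0392), with library totals (0.044) and with the GC and length correction (0.0415), and the list type I interferon response without a filter (0.0409) and with that correction (0.0371). The cause of these changes was not tested. Small changes were the most often missed in the simulation, where 44% of 1.2-fold changes were called. Only 200 of its 17697 genes were changed, so this share need not hold for these libraries. It also does not measure how secure the small changes called here are.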

Other observations

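The G1/S, G2/M and replication-dependent histone lists were fixed in advance. The other lists and the tests of patterns in this part were chosen after the results above were seen, and genes are named after their values were seen. Camera p-values of these later lists were adjusted over the later lists alone. As the lists were picked from these data, such p-values describe them and are no independent evidence. The later lists were not run under the alternative settings. Of 20 cytosolic aminoacyl-tRNA synthetase genes 16 were higher and 2 lower with baicalein (median log2 fold change 1.15, camera adjusted p = 0.000483, adjusted p = 0.258 with an estimated correlation), with 2.49 for WARS1 and 2.12 for GARS1. The 17 mitochondrial synthetase genes were 5 higher and 8 lower (median -0.08, camera adjusted p = 0.278). The medians of these 2 lists differed by 1.232, but the lists were picked for that contrast, so it says nothing about its origin. Amino acid transporters outside the ATF4 list were 9 higher and 2 lower of 11 (camera adjusted p = 0.00749, adjusted p = 0.262 with an estimated correlation), led by SLC6A9 (2.48) and SLC43A1 (2.04). Genes of secretory coats and the protein translocon were 22 higher and 2 lower of 26 (median 0.63, camera adjusted p = 2.82e-05, adjusted p = 0.258 with an estimated correlation), with 2.50 for SEC24D and 1.46 for SEC61A1. EGF family ligand genes were 8 higher and 0 lower of 9 (median 1.07, camera adjusted p = 0.00246, adjusted p = 0.383 with an estimated correlation), with 5.25 for EPGN and 3.18 for HBEGF. NRG3 had 0 counts in controls and 198 with baicalein, at least 54.5-fold higher by the 95% exact binomial limit, and the list's median is the same with NRG3 at that limit.

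Spliceosome core genes were 2 higher and 17 lower of 27 (median -0.29, camera adjusted p = 0.00749, adjusted p = 0.383 with an estimated correlation), with -0.99 for SNRPG and -0.98 for SNRPD3. Mitochondrial ribosomal protein genes were 6 higher and 20 lower of 32 (median -0.20, camera adjusted p = 0.0295, adjusted p = 0.262 with an estimated correlation), with -1.19 for MRPL16. Proteasome genes were 5 higher and 16 lower of 31 (camera adjusted p = 0.117). RNAs without a poly(A) tail were 0 higher and 1 lower of 8 in edgeR's quasi-likelihood test, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.278). The gene ENSG00000280614 was 4.15 times as high in control 1 as in control 2 (963 and 232 CPM), alongside RN7SK. With baicalein ENSG00000280614 had 176 and 152 CPM and did not pass (adjusted p = 0.226 in edgeR's quasi-likelihood test). The near-identical histone genes H2AC18 and H2AC19 had 37.2 and 14.5 CPM in baicalein 1 and 18.1 and 35.1 CPM in baicalein 2, while their sums were 51.6 and 53.2 CPM there and 19.3 and 20.2 CPM in the controls.

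Members of the G1/S and DNA replication list fell further than those of the G2/M and mitosis list (each list with adjusted p = 0.313 with an estimated correlation). Their mean log2 fold changes were -2.74 and -1.53, with a difference of -1.206 (SE 0.189, 30 genes each, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, with genes that are not independent replicates). With GC content and length trends removed the difference was -1.127 (SE 0.191), and with expression level in the model -1.176 (SE 0.192), which argues against either as the whole source. An accumulation of cells outside S phase is a candidate explanation for this order, but cell cycle phase was not measured in these libraries. A direct effect of the compound on transcription of replication genes stays open too.

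Of 15 replication-dependent histone genes 11 were higher and 2 lower, or 11 and 3 adjusted over the list alone (median log2 fold change 1.437, adjusted p = 0.632 with an estimated correlation), while all 30 tested DNA replication genes were lower. With GC content and length trends removed, the histone median was 1.454 over 14 genes and stayed above 0 in 99.8% of 10000 resamples of its members. Weaker selection of poly(A) RNA in the treated libraries would raise other RNAs without a tail, whose median was -1.35 (SD 1.316 over 8 genes), but 5 of these lay under 1 CPM in a group, and RN7SK was high in control 1 alone (33.3 CPM, against 4.53 in control 2 and 7.66 and 4.91 with baicalein). The abundant RN7SL1 and RN7SL2 had log2 fold changes of -0.19 and 0.02, which did not pass. The mitochondrial ribosomal RNA gene MT-RNR2 rose by 0.88. Of the 13 genes in the mitochondrially encoded list 7 were higher and 2 lower, or 1 and 1 with GC content and length corrected. Their median log2 fold change was 0.12 and the highest 0.60, so MT-RNR2 rose further than each of them. The list therefore does not account for the whole rise of MT-RNR2, and whether selection of poly(A) RNA did was not tested. With 5 of the 8 RNAs under 1 CPM and RN7SK uneven between the controls, weaker selection stays open. Reads shared among histone copies could move counts between single members, and more polyadenylated histone transcripts in cells that leave the cycle were not tested.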
